A study of Mus musculus with 9 samples.

How the data were processed

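Per the labels, the samples are livers of wild-type C57BL/6 mice, 8 weeks old and 20 g on average. The APAP group received acetaminophen (APAP, an analgesic whose overdose injures the liver) at 500 mg/kg by intraperitoneal injection. The dmPGE2+APAP group received dmPGE2, a stable analogue of prostaglandin E2, at 300 μg/kg by the same route 1 h before the same APAP dose, and the control group received saline. Livers were taken at 6 h, with 3 libraries per group. The control columns of the tables carry a name that the labels do not define, and they were assigned to the controls because the other columns name the treated groups. The labels' protocols describe total RNA from which ribosomal RNA was removed and a second strand marked with dUTP, so the libraries keep the strand. Whether the quantification used it is not recorded, so overlapping and antisense transcripts are read as uncertain. The series title also names miRNA and circular RNA, which are not analysed here.

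HISAT2 and the build GRCm38 (mm10) are named in the submitters' processing notes. The quantifier, the annotation release and any filter are not recorded. The deposited FPKM tables give, per the file headers, a value per gene for mRNA and a value per transcript for lncRNA. Of 21870 genes in the mRNA table, 21762 were matched to the GENCODE annotation, 92.5% of them with the same coordinates, and 21712 were protein-coding. Of 54836 transcripts in the lncRNA table, 35682 are isoforms of protein-coding genes, 81 of them annotated as protein-coding, and 16443 belong to non-coding genes. The other 2711 are absent from the GENCODE annotation and are called assembled here. Retained introns make up 21838 of the 54836 transcripts.

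The tables deposited as read counts hold a score and not counts. Each lncRNA score equals the FPKM times the genomic span of the locus, introns included, times a constant of 60.04 to 78.55 per library, rounded up. This held within 1% for all transcripts with a score of 1000 or more, and at least 99.3% of the smaller scores left a remainder between 0 and 1. The mRNA scores sum to between 296.8 M and 399.3 M per library. The constants imply 30 to 39.3 M fragments per library, but with annotated transcript lengths only 16.8% to 18.5% of lncRNA values between 0.5 and 3.5 fragments came within 0.05 of a whole number. Read counts were therefore not recovered, the counting error of a value is unknown, and no depth-based interval or floor is given. A test on counts had been planned and could not be used, and it was replaced by limma 3.58.1 in R 4.3.3 on FPKM.

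FPKM values of each library were divided by a scale factor, 0.1 was added and the log2 was taken. The factor was an unweighted trimmed mean of log ratios (30% trimmed by ratio, 5% by abundance), from the mRNA table for mRNA and from both tables together for lncRNA. The rescaling moved the log2 difference of APAP from control by 0.122 for mRNA and by −0.0509 for lncRNA. For dmPGE2+APAP against APAP the shifts were 0.0318 and 0.0916, and for dmPGE2+APAP against control they were 0.154 and 0.0407. All fold changes are relative to these shifts. Genes with at least 0.5 FPKM and transcripts with at least 0.1 FPKM in at least 3 libraries were tested, which left 11557 genes and 22984 transcripts. All 9 libraries entered a fit of 3 group means in limma with an abundance trend (6 residual degrees of freedom), with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Group means and standard deviations are of the deposited FPKM, and folds come from the rescaled log2 values. The added 0.1 makes the folds of genes near that level too small. With 3 against 3 libraries, an exact test of a single gene cannot give a p under 0.1, so each call rests on the spread that limma pools across genes.

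Gene lists for this tissue and treatment were tested with camera of limma, with a preset correlation of 0.01 between genes, where at least 5 members were measured. The tests were repeated with an estimated correlation, for which camera uses only the 6 residual degrees of freedom and is stricter. They were also repeated with fry, which asks whether a list's genes move one way on balance. The lists cover immediate early genes, the integrated stress response, heat shock, p53 targets, cAMP and CREB targets, NRF2 and glutathione, hypoxia, ferroptosis, ER chaperones, cell death, the acute phase, NF-kB cytokines and adhesion, and the interferon response. They also cover pericentral and periportal hepatocytes, hepatocyte secreted and identity genes, cytochrome P450 and phase II, bile acids, cholesterol synthesis, lipogenesis, fatty acid oxidation, gluconeogenesis and fasting, complement and coagulation, the circadian clock, the cell cycle, cytosolic ribosomal proteins, the mitochondrial genome and the prostaglandin pathway. Markers of other cells cover neutrophils, monocytes, Kupffer cells, lymphocytes, erythroid cells and platelets, stellate cells, sinusoidal endothelium, cholangiocytes and exocrine pancreas, and a list of named lncRNAs was read in the lncRNA table. Lists share members: Atf3, Fos, Gdf15, Hmox1 and Pdk4 each stand in more than a single list.

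The groups, comparisons, lists, gene panel, the rule for named genes and most alternatives were fixed before the data were examined. The pseudocount, filters and scaling were set from the units and value ranges, before any differential result was seen. Named genes are a panel for APAP injury and prostaglandin signalling, and the 6 largest rises and 6 largest falls among calls with a group mean of at least 5 FPKM, no overlap between the groups' libraries and a proper symbol. For dmPGE2+APAP against control 4 and 4 were taken, and for lncRNA 5 and 5 with a mean of at least 1 FPKM. The rule had been written for read counts scaled by depth and was carried over to FPKM. Where no gene passed, the smallest p values are named and said not to pass. Up to 4 members of each list with the smallest p serve as examples.

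Whether dmPGE2 reversed APAP changes was measured on the genes called in APAP against control, as the number called the opposite way in dmPGE2+APAP against APAP and as the share shifted toward control. Both comparisons use the APAP libraries, so the same values were simulated with no dmPGE2 effect in 50 draws. The code was tested on simulated data with 200 changed genes. Alternatives were other scalings, other pseudocounts, other filters, only the groups compared, a block for the replicate number, each library left out in turn, and the deposited score tables.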

Results

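Liver RNA was measured in 3 groups of 3 mice: saline controls, mice given an overdose of APAP, and mice given dmPGE2 before the same overdose. Deposited FPKM summed to between 371958.2 and 393937.6 per library over the mRNA table and to between 22558.5 and 30436.9 over the lncRNA table. Between 9979 and 10321 genes per library reached 1 FPKM. Albumin mRNA alone took 5.6% to 8.33% of the mRNA FPKM of a library. The depth is not known. If the constants above count both reads of each fragment, it was 30 to 39.3 M fragments per library. The first principal component of the tested mRNAs (51.2% of the variance) separated the 6 treated libraries from the controls. On the second (12.6%), control replicate 3 lay at 32.43 and the other controls at −15.42 and −16.08.

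**Figure D1:**
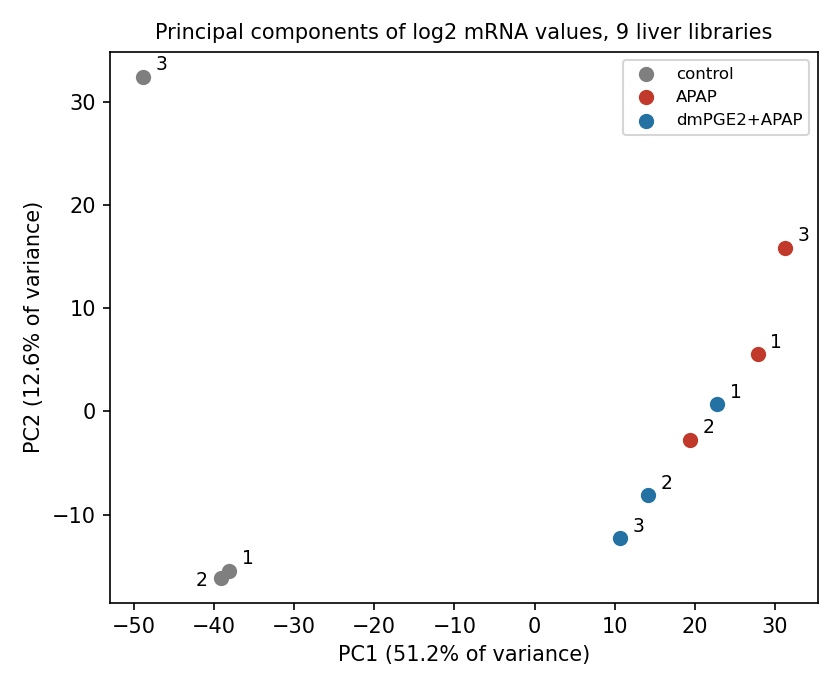
Principal components of log2(FPKM + 0.1) over the 11557 tested genes, component 1 (51.2% of the variance) on the x axis and component 2 (12.6%) on the y axis, a point per library with colour by group and the replicate number beside it. The controls lie at negative values of component 1, from −38.07 to −48.91, and the treated libraries at positive values, and control replicate 3 lies apart on component 2 at 32.43.

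The comparison of APAP with control asks which liver transcripts respond to the overdose by 6 h. Atf3, a transcription factor induced by many kinds of stress (ENSMUSG00000026628, GRCm38 chromosome 1, from 191170296 to 191218039), was at 105 ± 13.9 FPKM in APAP livers and 0.373 ± 0.197 in controls (mean ± SD, n = 3 per group here and throughout). This was a 249-fold rise (log2 7.96, SE 0.298, limma adjusted p = 1.82e-06). Gdf15, a secreted stress cytokine (chromosome 8, from 70629393 to 70632456), rose 86.5-fold to 172 ± 16.7 FPKM. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, from 29090976 to 29100727), rose 92.1-fold to 112 ± 8.95 FPKM (log2 6.52, and 5.71 without control replicate 3). The AP-1 gene Fos rose 119-fold, the lipid droplet gene Hilpda 98.3-fold and the transcription factor gene Egr1 92.9-fold (log2 6.54, and 7.20 without control replicate 3). Hmox1, the inducible haem oxygenase (chromosome 8, from 75093621 to 75100589), rose 32.3-fold to 303 ± 47.3 FPKM. Glul, the glutamine synthetase of the hepatocytes next to the central vein (chromosome 1, from 153899944 to 153909723), fell from 415 ± 53.5 to 157 ± 36 FPKM, 0.408 of the control level (adjusted p = 0.00277).

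Of the 11557 genes tested, 2393 passed, 1307 higher and 1086 lower in APAP livers (54.6% higher). At least 2-fold changes were fitted for 688 of them, 501 up and 187 down. At an unadjusted p under 0.05 there were 4097 genes, where chance gives 578. On deposited FPKM with no rescaling 3081 genes passed and 31.6% of them were higher, so the split into rises and falls depends on the scaling. Without APAP replicate 3, 1532 genes passed.

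All 19 immediate early genes, which respond first to stimuli, rose (19 adjusted over the list alone, median log2 fold change 3.47, camera adjusted p = 1.54e-21, and adjusted p = 0.175 with an estimated correlation). Jun went from 6.18 ± 2.27 to 154 ± 5.54 FPKM (27.8-fold) and Klf6 rose 9.25-fold. In the integrated stress response, which lowers translation and induces ATF4 targets, 12 of 15 genes rose and none fell (14 adjusted over the list alone, median 2.33, adjusted p = 2.86e-13). This was the single list that also passed with an estimated correlation (adjusted p = 0.0119). Atf4 rose 2.18-fold to 70.6 ± 3.2 FPKM and Ddit3, which encodes the stress factor CHOP, rose 5.71-fold to 7.75 ± 0.758 FPKM. Heat shock genes, chaperones for unfolded proteins, rose in 11 of 14 cases (12 adjusted over the list alone, median 1.56, adjusted p = 1.41e-08, and adjusted p = 0.198 with an estimated correlation). Hspa8 went from 251 ± 18.1 to 678 ± 106 FPKM (2.92-fold), Hsph1 rose 3.34-fold and Hspb8 2.96-fold, while Hspa1a is uncertain because a near-identical copy shares its reads. Of 16 p53 targets 9 rose and Ccng1 fell (10 adjusted over the list alone, median 1.01, adjusted p = 2.28e-06, and adjusted p = 0.175 with an estimated correlation). Among them Btg2, an antiproliferative gene, rose 67.6-fold and Mdm2, the ubiquitin ligase that limits p53, rose 4.41-fold. Of 16 cAMP and CREB targets 10 rose (10 adjusted over the list alone, median 1.28, adjusted p = 6.54e-07, and adjusted p = 0.175 with an estimated correlation). They include the nuclear receptor gene Nr4a1 (65.1-fold) and the MAP kinase phosphatase gene Dusp1 (10.2-fold).

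Antioxidant genes moved less uniformly. Of 19 NRF2 and glutathione genes 8 rose (adjusted over the list alone, 9 higher and 2 lower), with a median log2 fold change of 0.431 (adjusted p = 0.0111, and adjusted p = 0.411 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose 6.12-fold and Gclc, the catalytic subunit of glutathione synthesis, rose 2.31-fold from 56.7 ± 16.8 to 118 ± 17.7 FPKM. The NRF2 targets Gclm (29.2 ± 5.81 against 44.2 ± 2.07 FPKM, adjusted p = 0.256) and Nqo1 (2 ± 0.263 against 2.69 ± 1.14 FPKM, adjusted p = 0.606) did not pass. Gclm-202, an isoform listed among the lncRNA entries, was at 0.0789, 0.0856 and 0.045 FPKM in controls and 19.6, 9.44 and 20.3 FPKM in APAP livers. The Gclm value may therefore leave out part of the gene's RNA. Of 17 hypoxia genes 5 rose (5 adjusted over the list alone, median 0.341, adjusted p = 0.00878, and adjusted p = 0.175 with an estimated correlation). The glucose transporter gene Slc2a1 rose 2.43-fold, the collagen hydroxylase gene P4ha1 2.19-fold and Ndrg1 2.11-fold. Of 18 ferroptosis genes 7 rose and 3 fell (10 adjusted over the list alone, median 0.267, adjusted p = 0.0704). Slc40a1, the iron exporter, fell from 49 ± 4.56 to 17 ± 2.53 FPKM. Of 17 ER chaperones 3 rose (adjusted over the list alone, 5 higher and 1 lower, median 0.123, adjusted p = 0.162), Hspa5 by 1.96-fold. In the acute phase list the metal-binding genes Mt1 and Mt2 rose 29.2-fold and 85.1-fold and Hamp, the iron hormone hepcidin, fell from 790 ± 219 to 241 ± 33.6 FPKM. Control replicate 3 was low for both metal-binding genes, and without it their log2 fold changes fell from 4.87 to 3.83 and from 6.41 to 4.90, while without control replicate 1 they were 5.70 and 7.37. Mt1, Mt2 and Hamp were the 3 of 22 members called (3 adjusted over the list alone, median 0.132, adjusted p = 0.679).

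Of 14 NF-kB cytokine and adhesion genes 8 rose (11 adjusted over the list alone, median 1.05, adjusted p = 2.57e-05, and adjusted p = 0.198 with an estimated correlation). The neutrophil chemokine gene Cxcl2 rose 16.8-fold, the NF-kB cofactor gene Nfkbiz 6.49-fold and the adhesion gene Vcam1 2.31-fold. Cxcl1, a related chemokine, rose 5.12-fold (10.3 ± 5.16 against 1.89 ± 0.275 FPKM, adjusted p = 0.0208). This call was lost without control replicate 1 or 2 or APAP replicate 1 or 3 (adjusted p of 0.0558, 0.0592, 0.0665 and 0.0796). The cytokine gene Il1b (2.56 ± 1.23 against 1.25 ± 0.451 FPKM, adjusted p = 0.137) did not pass. Of 7 neutrophil markers 5 rose (6 adjusted over the list alone, median 2.14, adjusted p = 0.000373, and adjusted p = 0.342 with an estimated correlation). Levels were low, as for Clec4d (6.8-fold, to 0.768 ± 0.204 FPKM). The list holds 15 genes, and those below the filter were not tested. Clec4d reached 0.5 FPKM in the APAP libraries alone. Members that pass the filter in this way favour a rise here and a fall with dmPGE2. In the interferon list 1 of 15 genes rose and 1 fell (2 adjusted over the list alone, median −0.361, adjusted p = 0.138). The chemokine gene Cxcl10 rose 3.65-fold, a call lost without control replicate 1 or 2 or APAP replicate 1 or 3 (adjusted p from 0.0529 to 0.0861).

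Of 9 erythroid and platelet genes 6 rose (8 adjusted over the list alone, median 1.08, adjusted p = 2.34e-05, and adjusted p = 0.187 with an estimated correlation). The platelet chemokine gene Pf4 (chromosome 5, from 90772435 to 90773383) went from 0.529 ± 0.0882 to 3.55 ± 0.443 FPKM (6.25-fold). Ppbp, another platelet chemokine gene, rose 17.3-fold, and Itga2b, the platelet integrin gene, rose 3.98-fold. The globin genes, which share reads with near-identical copies and are uncertain, had a median log2 fold change of 0.952 against 2.64 for the platelet genes. Of 14 Kupffer cell markers Cd68 rose 1.69-fold and Slc40a1 fell (2 adjusted over the list alone, median −0.164, adjusted p = 0.36). Of 5 monocyte markers 0 passed with limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, median −0.229, camera adjusted p = 0.431, fry adjusted p = 0.243). Of 15 stellate cell markers 3 rose (3 adjusted over the list alone, median 0.527, adjusted p = 0.0111, and adjusted p = 0.491 with an estimated correlation). Among them were the hepatocyte growth factor gene Hgf (1.75-fold) and the matrix gene Dcn (1.44-fold). The stellate call was lost without control replicate 2 (adjusted p = 0.0509). Of 6 cholangiocyte markers Sox9 rose 5.67-fold (adjusted over the list alone, 1 higher and 1 lower, median 0.424, adjusted p = 0.355). The exocrine pancreas and lymphocyte lists had too few expressed members to test. In control, APAP and dmPGE2+APAP livers the exocrine pancreas sums were 9.03, 4.79 and 5.88 FPKM and the lymphocyte sums 3.87, 2.09 and 2.12 FPKM, highest in controls.

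Genes of pericentral hepatocytes, the zone in which APAP is activated and which it injures first, were lower. Of 18 such genes 7 fell and none rose (8 adjusted over the list alone, median log2 fold change −0.601, adjusted p = 0.000327, and adjusted p = 0.198 with an estimated correlation). Glul and the secreted factor gene Lect2 (0.415 of control) were among them. Cyp2e1, the main enzyme that turns APAP into its reactive product, was at 2650 ± 327 FPKM against 3450 ± 621 in controls and did not pass (adjusted p = 0.404). Cyp2a5, a pericentral cytochrome P450 gene (chromosome 7, from 26835305 to 26843548), fell from 265 ± 65.5 to 39.2 ± 15.4 FPKM. Among the 20 genes of the cytochrome P450 and phase II list 2 fell, Cyp2c50 and Cyp2c37, which share reads with close relatives (0 of the list adjusted over the list alone in limma, 7 at an unadjusted p under 0.05, median −0.156, adjusted p = 0.314, fry adjusted p = 0.323). Both calls were lost without control replicate 1 or 2 or APAP replicate 1 or 3, and that of Cyp2c50 also without control replicate 3 (adjusted p from 0.053 to 0.13). Of 14 bile acid genes 4 fell (4 adjusted over the list alone, median −0.243, adjusted p = 0.163). The bile acid receptor gene Nr1h4 fell from 50.2 ± 8.13 to 27.3 ± 2.84 FPKM and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, from 6264197 to 6275633), from 33.8 ± 14.2 to 4.82 ± 2.5 FPKM (adjusted p = 0.0243). The Cyp7a1 call was lost without control replicate 2 or 3 or APAP replicate 1 (adjusted p of 0.0735, 0.0551 and 0.0799). Of the other falls, the transporter gene Slc10a1 lost its call without control replicate 2 or 3 or APAP replicate 1 or 3 (0.0593 to 0.091) and the conjugating enzyme gene Baat without control replicate 1 or 2 or APAP replicate 1 or 3 (0.093 to 0.111), so without APAP replicate 1 only that of Nr1h4 among the 4 is left.

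In lipid and fasting metabolism, Pdk4, the kinase that spares glucose, rose 43.9-fold from 1.97 ± 0.706 to 82.2 ± 22 FPKM, and Plin2, the lipid droplet coat gene (chromosome 4, from 86648386 to 86670060), rose 3.04-fold to 527 ± 44.9 FPKM. With the hepatokine gene Fgf21 (9.52-fold) they are the 3 of 21 fatty acid oxidation genes that rose (3 adjusted over the list alone, median 0.381, adjusted p = 0.00298, and adjusted p = 0.647 with an estimated correlation). Of 15 gluconeogenesis and fasting genes 5 rose (6 adjusted over the list alone, median 0.451, adjusted p = 0.00546, and adjusted p = 0.58 with an estimated correlation). Among them were Igfbp1, an insulin-repressed gene (21.5-fold, to 810 ± 100 FPKM), and Irs2 (1.83-fold). Of 20 cholesterol synthesis genes 6 fell (6 adjusted over the list alone, median −0.618, adjusted p = 0.0111, and adjusted p = 0.691 with an estimated correlation). Fdft1, the squalene synthase gene, went from 12.9 ± 4.19 to 6.15 ± 0.942 FPKM, a call lost without control replicate 2 or 3 or APAP replicate 1 or 3 (adjusted p from 0.0657 to 0.0953). Control replicate 3 stood apart on these lists: its median deviation from the other controls was 0.995 for lipogenesis, 0.588 for cholesterol synthesis, −0.824 for fatty acid oxidation and −0.946 for gluconeogenesis and fasting (log2). Without it the calls of fatty acid oxidation (adjusted p = 0.14), gluconeogenesis and fasting (adjusted p = 0.0763) and cholesterol synthesis (adjusted p = 0.111) were lost, the last also without control replicate 2 (adjusted p = 0.0608). Of 15 lipogenesis genes Elovl6 fell (0 adjusted over the list alone in limma, 4 at an unadjusted p under 0.05, median −0.312, adjusted p = 0.245, fry adjusted p = 0.471), a call lost without control replicate 2 or APAP replicate 2 or 3 (adjusted p from 0.0508 to 0.0726).

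The largest falls were those of Dbp, a clock output gene (0.0985 of control, chromosome 7, from 45705088 to 45710203), Nrep (0.105), the hepatocyte transcription factor gene Onecut1 (0.142), Cyp7a1 (0.151), Cyp2a5 (0.157) and the thyroxine carrier gene Serpina7 (0.182). For several of them control replicate 3 raised the control mean: Dbp was at 19.4, 21.2 and 61.8 FPKM in control replicates 1 to 3, Nrep at 1.58, 2.19 and 15.3 and Onecut1 at 4.76, 4.30 and 25.7. Without that library the log2 fold change of Nrep went from −3.25 to −2.31 and that of Onecut1 from −2.82 to −2.04, and without control replicate 1 that of Nrep was −3.84. Among genes of the prostaglandin pathway 3 of 11 fell (3 adjusted over the list alone, median −0.158, adjusted p = 0.29). Hpgd, which degrades prostaglandin E2, fell from 49.8 ± 5.99 to 28.3 ± 4.43 FPKM (adjusted p = 0.0106), and Ptgs1, a cyclooxygenase gene, fell to 0.731 of control (adjusted p = 0.00824). The receptor gene Ptger4 (0.593 ± 0.0911 against 0.528 ± 0.156 FPKM) and the transporter gene Slco2a1 (13.2 ± 0.499 against 13.6 ± 1.25 FPKM) did not pass (adjusted p of 0.504 and 0.542). The other receptor genes Ptger1, Ptger2 and Ptger3 and the inducible cyclooxygenase gene Ptgs2 were below the filter, with highest values of 0.457, 0.497, 0.177 and 0.0594 FPKM. Albumin mRNA was at 28600 ± 2700 against 23000 ± 1340 FPKM and did not pass (adjusted p = 0.236). Of 22 complement and coagulation genes 0 passed with limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, median 0.0352, camera adjusted p = 0.659, fry adjusted p = 0.571). Of 20 cytosolic ribosomal protein genes Rpl10a rose 1.27-fold, a call lost without control replicate 2 or APAP replicate 1, 2 or 3 (adjusted p from 0.0596 to 0.129), and the list did not pass (0 adjusted over the list alone in limma, 1 at an unadjusted p under 0.05, median 0.0969, adjusted p = 0.162, fry adjusted p = 0.194). Of 11 mitochondrial genes 1 rose and 1 fell (2 adjusted over the list alone, median 0.214, adjusted p = 0.659), both of them, mt-Nd1 and mt-Nd2, uncertain because near-identical nuclear copies can share their reads. The mt-Nd1 call was lost without APAP replicate 1 (adjusted p = 0.0501) and that of mt-Nd2 without control replicate 1 or APAP replicate 2 or 3 (0.059 to 0.0674).

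**Figure D2:**
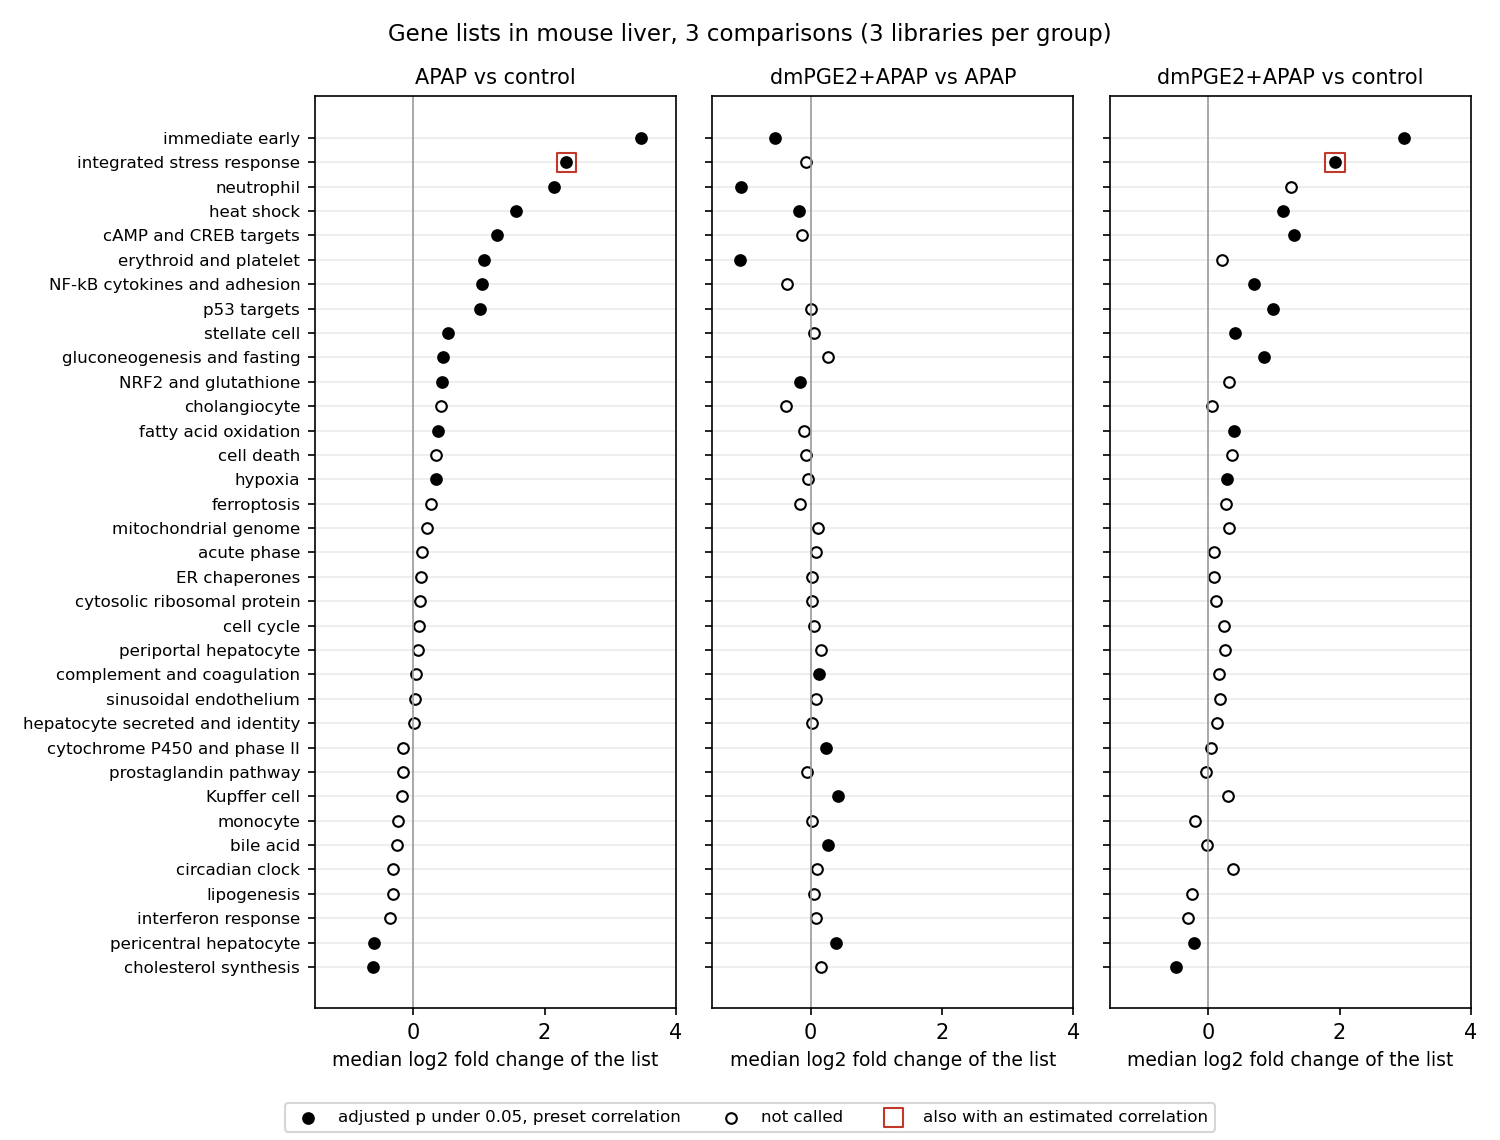
Median log2 fold change of each of the 35 gene lists tested in the 3 comparisons, a panel per comparison, with filled points for lists that passed camera at the preset correlation open points for those that did not and a red square around those that also passed with an estimated correlation. In APAP against control 15 lists passed (13 higher, 2 lower), in dmPGE2+APAP against APAP 10 (5 and 5) and in dmPGE2+APAP against control 12 (10 and 2), and 1, 0 and 1 of them have the red square.

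Among lncRNA table entries, the assembled transcript LINC190 (TCONS_00063140, chromosome 13, from 55184447 to 55191756) was listed at 0 in all 3 controls and at 18.4, 40.1 and 11.7 FPKM in APAP livers (adjusted p = 0.000322). Chka-211, a non-coding isoform of the choline kinase gene (ENSMUST00000146463, chromosome 19, from 3875379 to 3884538), rose 60.3-fold from 0.474 ± 0.32 to 31.6 ± 8.4 FPKM (adjusted p = 0.00164). Also among the largest rises were those of Gclm-202 (16.5 ± 6.09 against 0.0698 ± 0.0218 FPKM, adjusted p = 0.0292), Pxn-210 (listed at 0 in controls, 8.53, 8.74 and 8.5 FPKM in APAP livers, adjusted p = 0.0406) and Ube4b-209 (listed at 0 in controls, 5.34, 4.51 and 5.78 FPKM, adjusted p = 0.0313). The largest falls were to 0.0198 of control for Dynlrb1-201 (adjusted p = 0.019), 0.0404 for AC157910.3-201, 0.0527 for Clcn3-209, 0.0618 for Inmt-202 and 0.0709 for Slc39a7-202 (adjusted p = 0.0303). Of these, Gclm-202, Pxn-210 and Ube4b-209 no longer passed when any library of the pair was left out (adjusted p from 0.0612 to 0.119). Dynlrb1-201 was lost when any control was left out or without APAP replicate 1 or 2 (0.0543 to 0.0694), and Slc39a7-202 without control replicate 1 or 3 or APAP replicate 1 or 3 (0.0951 to 0.0975).

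Of 22984 transcripts tested 824 passed in APAP against control, 603 higher and 221 lower, all of them by at least 2-fold, and 4239 had an unadjusted p under 0.05 (1149 by chance). The split depends on the scaling: with factors from the mRNA table alone, chosen after seeing the data, 834 were higher and 181 lower (82.2% higher), and with factors from the lncRNA table alone 484 and 276 (63.7%). Isoforms of protein-coding genes made up 618 of the calls (454 higher, 164 lower), and for 351 of these the parent gene was called in the same direction. Transcripts of non-coding genes made up 83 (51 higher, 32 lower) and assembled transcripts 123 (98 higher, 25 lower). Leaving out a library lowered the count to 270, 296 and 340 without control replicates 1 to 3, and to 181, 454 and 240 without APAP replicates 1 to 3. In the named lncRNA list, overlapping isoforms of a gene such as Gas5 count as separate members and are not independent. The preset correlation does not allow for this, and the list's p values are not adjusted for the other lists, in any comparison. Of 72 measured transcripts of 17 named lncRNA genes 2 rose (2 adjusted over the list alone, median log2 fold change 0.397, camera p = 0.00736, and p = 0.0332 with an estimated correlation). These were Snhg3-205, a host of small nucleolar RNA, at 1.42 ± 0.741 FPKM against 0.094 ± 0.163 (adjusted p = 0.0223), and Neat1-204, an isoform of the paraspeckle RNA, listed at 0 in the controls and at 0.427, 0.241 and 0.764 FPKM in APAP livers (adjusted p = 0.0379). Without a library the fitted log2 fold changes ran from −5.07 (APAP replicate 1) to −6.78 (APAP replicate 3) for Dynlrb1-201. For Slc39a7-202 they ran from −3.18 (APAP replicate 1) to −4.61 (control replicate 2). They reached 5.32 for Chka-211 (control replicate 3), −5.23 for AC157910.3-201 (control replicate 2) and 3.76 for Snhg3-205 (control replicate 1). The Neat1-204 call was lost when any library of the pair was left out (adjusted p from 0.0548 to 0.132), and that of Snhg3-205 without control replicate 2 or 3 or APAP replicate 2 or 3 (0.0596 to 0.0823).

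The comparison of dmPGE2+APAP with APAP asks what the prostaglandin analogue, given before APAP, changes in the liver. No group received dmPGE2 alone, so its own effects cannot be told apart from a change in the injury. No single mRNA passed, and the values below are levels of genes that did not. Arl4d, a small GTPase gene (chromosome 11, from 101665532 to 101667832), was at 50.9 ± 14.5 FPKM with dmPGE2 and 15.1 ± 2.76 without (3.36-fold, log2 1.75, SE 0.209, adjusted p = 0.151). Upp2, a uridine phosphorylase gene (chromosome 2, from 58567298 to 58792971), was at 109 ± 37.8 against 33.4 ± 6.13 FPKM (3.21-fold, adjusted p = 0.165). Coq9, a gene of ubiquinone synthesis, was at 17 ± 0.801 against 27.5 ± 1.66 FPKM (0.634 of APAP), and Ube2l6 at 7.01 ± 0.345 against 13.7 ± 2.51 FPKM (0.533). Tmem173, which encodes STING, an adaptor in the sensing of cytosolic DNA, was at 0.402 of APAP and the helicase gene Blm at 1.95-fold the APAP level, all 4 with adjusted p between 0.151 and 0.165.

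With limma 0 of 11557 mRNAs passed (smallest adjusted p = 0.151), and 1082 had an unadjusted p under 0.05, 549 higher and 533 lower, which is 1.87 times the number given by chance. In simulated data of this design the test recovered 32.8% of 1.5-fold, 76.1% of 2-fold and 95.5% of 4-fold changes. The noise was drawn independently per gene from limma's pooled spread, and 200 genes were changed. The simulation for the reversal below called more genes than were observed, so the real shares may be lower. When only these groups were fitted 2 genes passed, Nek7 (log2 −1.76) and G0s2 (log2 −1.71, adjusted p = 0.00126 each). Without dmPGE2+APAP replicate 1, which lay midway between the treated groups, 42 genes passed (12 higher, 30 lower), among them Ppbp (log2 −3.18, adjusted p = 0.000112), Arl4d (log2 1.98, adjusted p = 0.00521), Upp2 (log2 2.0, adjusted p = 0.00531) and Pf4 (log2 −1.70, adjusted p = 0.0099). Without APAP replicate 2, which lay as near the middle (0.498 against 0.495 on the axis described below), Gm20708 and Zfp422 passed (2 genes). Without APAP replicate 3 Zfp358 passed (1 gene). These genes were named after their values were seen. Leaving out a midway library widens the difference between the groups by construction, so the 42 genes are not a better measure of the effect.

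As lists, some markers of other cells differed with dmPGE2. The erythroid and platelet list had a median log2 fold change of −1.08 (adjusted p = 2.96e-09, and adjusted p = 0.274 with an estimated correlation). Over all genes 0 of its 9 genes passed, and 8 did adjusted over the list alone, all lower. Pf4 was at 1.26 ± 0.433 FPKM against 3.55 ± 0.443 without dmPGE2 (adjusted p = 0.174), Ppbp at 1.52 ± 1.42 against 7.23 ± 0.688 and Itga2b at 0.568 of the APAP level, while Hba-a1, uncertain for its near-identical copy, was at 0.473. Neutrophil markers were lower as a list too (median −1.06, 3 of 7 adjusted over the list alone, adjusted p = 3.7e-05, and adjusted p = 0.583 with an estimated correlation). The receptor gene Csf3r was at 0.465 and the gelatinase gene Mmp9 at 0.42 of the APAP level. Kupffer cell markers were higher (median 0.42, 2 higher and 1 lower of 14 adjusted over the list alone, adjusted p = 0.00031, and adjusted p = 0.583 with an estimated correlation), for example the macrophage receptor gene Csf1r at 1.39-fold. APAP replicate 3 carries much of this: Adgre1, the F4/80 gene (chosen after its values were seen), was at 6.99, 5.77 and 3.62 FPKM in APAP replicates 1 to 3 and at 7.08, 6.31 and 6.43 FPKM with dmPGE2. Without APAP replicate 3 the list still passed, with a larger adjusted p (0.00797). The neutrophil call was lost without APAP replicate 1 (adjusted p = 0.176).

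Several stress lists were lower and several hepatocyte lists higher with dmPGE2. Immediate early genes were lower (median −0.547, 3 of 19 adjusted over the list alone, adjusted p = 2.65e-05, and adjusted p = 0.583 with an estimated correlation). The AP-1 genes Fosl1 and Fosb were at 0.272 and 0.312 of the APAP level. Heat shock genes were lower (median −0.186, 1 of 14 adjusted over the list alone, adjusted p = 0.00717, and adjusted p = 0.583 with an estimated correlation), Hspa8 at 440 ± 47.6 against 678 ± 106 FPKM. NRF2 and glutathione genes were lower (median −0.168, adjusted p = 0.026, and adjusted p = 0.583 with an estimated correlation), Srxn1 at 0.32 of the APAP level. Pericentral genes were higher (median 0.384, 2 of 18 adjusted over the list alone, adjusted p = 0.00636, and adjusted p = 0.583 with an estimated correlation), Glul at 259 ± 32.1 against 157 ± 36 FPKM (adjusted p = 0.324). Bile acid genes were higher (median 0.257, adjusted p = 0.00717, and adjusted p = 0.583 with an estimated correlation), Cyp7a1 at 33.3 ± 24.4 against 4.82 ± 2.5 FPKM (adjusted p = 0.339). The cytochrome P450 and phase II list (median 0.228, adjusted p = 0.026, and adjusted p = 0.583 with an estimated correlation) and the complement and coagulation list (median 0.128, adjusted p = 0.0274, and adjusted p = 0.583 with an estimated correlation) were higher, with Cyp3a11 at 1.69-fold. In the NRF2, bile acid, P450 and complement lists 0 genes passed adjusted over the list alone in limma, and 5, 2, 3 and 0 had an unadjusted p under 0.05.

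In all, 10 of 35 lists passed camera at the preset correlation, 5 higher and 5 lower, 16 had an unadjusted p under 0.05, and 0 passed either with an estimated correlation (1 unadjusted) or in fry (4 unadjusted, smallest adjusted p = 0.0525). The fold changes of this comparison also followed transcript length and GC content across genes (rho of −0.166 and −0.114), and APAP replicate 3 deviated from the other APAP libraries with length (rho = 0.298). Only the erythroid and platelet, immediate early and Kupffer cell calls held under each library left out. Without APAP replicate 1, 3 lists passed, and NRF2 (adjusted p = 0.129), bile acid (0.0987), complement (0.176), P450 (0.176), heat shock (0.347), neutrophil (0.176) and pericentral (0.0999) calls were lost. NRF2 was also lost without dmPGE2+APAP replicate 3 (0.175), heat shock without dmPGE2+APAP replicate 2 (0.117), P450 without APAP replicate 3 (0.137) or dmPGE2+APAP replicate 3 (0.0545), and complement without APAP replicate 3 (0.0699) or dmPGE2+APAP replicate 1 (0.112) or 3 (0.0642). Among lists that did not pass, NF-kB genes had a median of −0.358 (adjusted p = 0.0583), with Il1b at 0.693 ± 0.348 against 2.56 ± 1.23 FPKM and Cxcl1 at 3.18 ± 2.95 against 10.3 ± 5.16 FPKM (adjusted p of 0.324 and 0.396). Fatty acid oxidation genes had a median of −0.107 (adjusted p = 0.0642), with Plin2 at 276 ± 44.6 against 527 ± 44.9 FPKM and Pdk4 at 22.9 ± 11.7 against 82.2 ± 22 FPKM (adjusted p of 0.213 and 0.308). For p53 targets the median was above 0 (0.00453) and the mean (−0.124) and the test below it, and the acute phase, ribosomal, stellate cell, monocyte, ER chaperone and hepatocyte identity lists also had a median, mean or test of differing sign.

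Of the panel, Hmox1 was at 209 ± 49.9 against 303 ± 47.3 FPKM (adjusted p = 0.529), Atf3 at 64.4 ± 22.8 against 105 ± 13.9 FPKM (adjusted p = 0.516), Gclc at 0.683 of the APAP level (adjusted p = 0.476) and Hpgd at 40.7 ± 3.02 against 28.3 ± 4.43 FPKM (adjusted p = 0.324). Ddit3 (1.37-fold), Cdkn1a (1.01-fold), Mt1 (1.09-fold), Cyp2e1 (1.2-fold), Alb (1.03-fold), Nqo1 (1.13-fold), Gclm (0.961), Slco2a1 (0.977) and Ptger4 (0.96) did not pass either. Hamp, hepcidin, was at 535 ± 107 against 241 ± 33.6 FPKM (adjusted p = 0.22). In the integrated stress list the serine synthesis gene Psat1 was at 0.366 of the APAP level and Ddit4, an inhibitor of mTORC1, at 3.7-fold (adjusted p of 0.212 and 0.324).

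**Figure D3:**
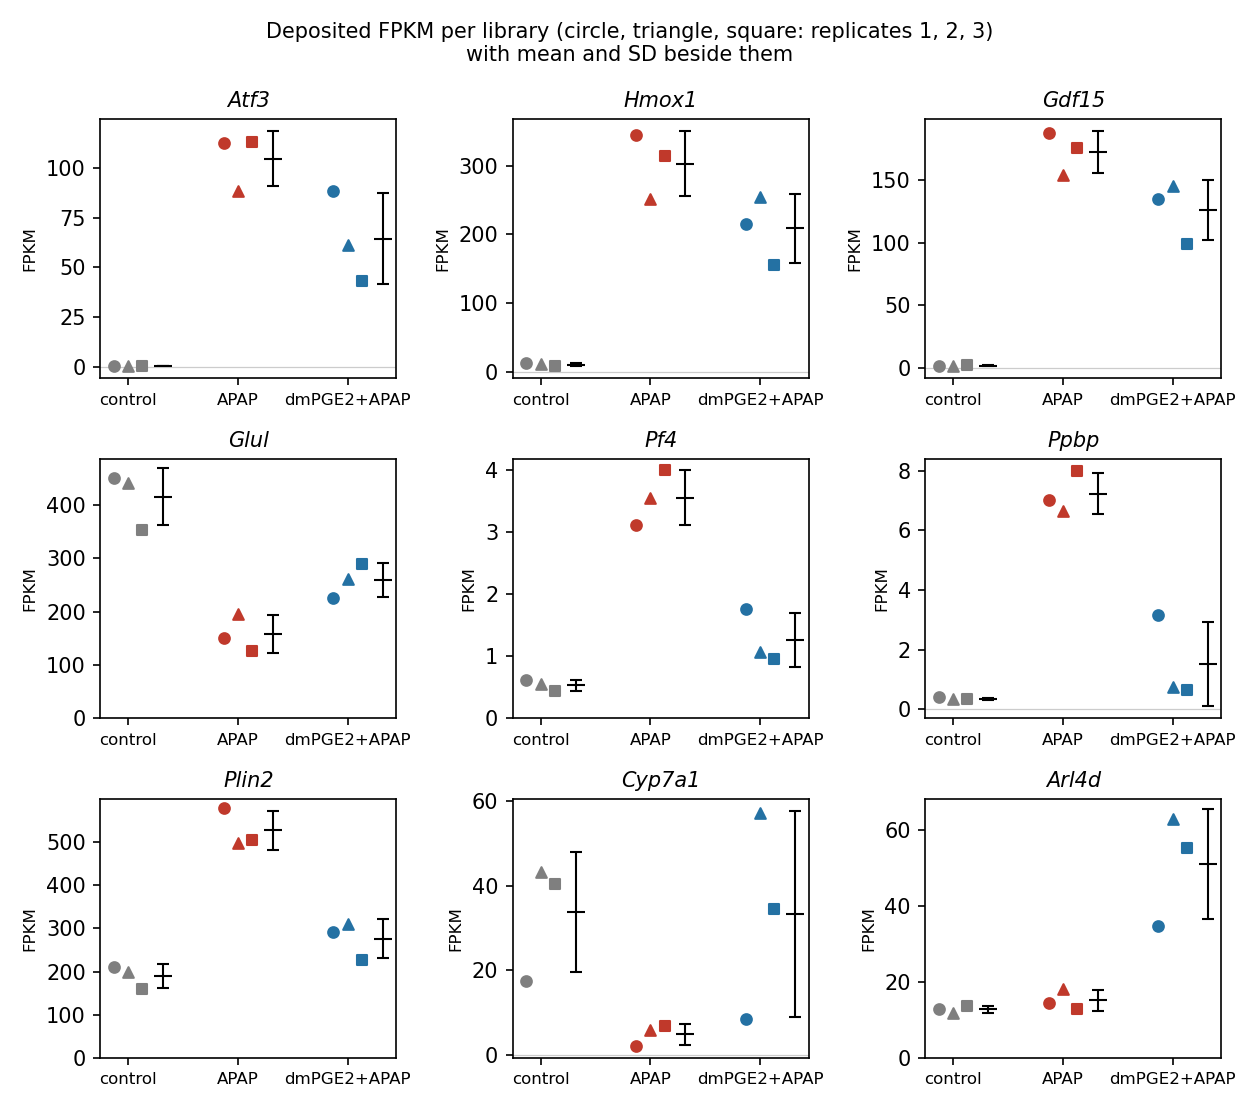
Deposited FPKM per library of 9 named genes in control, APAP and dmPGE2+APAP livers, with markers for replicates 1 to 3, a line for the group mean and whiskers for the SD beside them (n = 3), each panel on a linear axis from 0. Atf3 averages 0.373, 105 and 64.4 FPKM, Glul 415, 157 and 259 FPKM and Pf4 0.529, 3.55 and 1.26 FPKM in control, APAP and dmPGE2+APAP livers, and none of the differences between dmPGE2+APAP and APAP passed the test.

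Of the lncRNA table, 0 of 22984 transcripts passed with limma between dmPGE2+APAP and APAP (smallest adjusted p = 0.084), and 1482 had an unadjusted p under 0.05, where chance gives 1149. The smallest p values were those of Hdac1-203 (listed at 0 in APAP livers, 0.4, 0.401 and 0.448 FPKM with dmPGE2, adjusted p = 0.084) and of Arsg-OT1 (0.435 ± 0.119 against 0.00536 FPKM), Banf1-204 (0.48, 0.633 and 0.296 FPKM in APAP livers, listed at 0 with dmPGE2), Gsdme-OT1 (0.302, 0.469 and 0.351 FPKM in APAP livers, listed at 0 with dmPGE2) and Gm11827-201 (listed at 0 in APAP livers, 0.271, 0.601 and 0.74 FPKM with dmPGE2), each with an adjusted p of 0.0898. In simulated data with 200 changed transcripts 0% of 1.5-fold and 2-fold and 18.2% of 4-fold changes were recovered. Changes of these sizes in that few transcripts were thus mostly not detectable. Left-out libraries gave 2, 1 and 1 calls without APAP replicates 1 to 3 and 8, 2 and 1 without dmPGE2+APAP replicates 1 to 3, none of them among the 5 transcripts named here. Of the 72 named lncRNA transcripts 0 passed (0 adjusted over the list alone, median −0.0853, p = 0.611, and p = 0.62 with an estimated correlation).

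Against control, dmPGE2+APAP livers show the response to both treatments together. Atf3 was 151-fold above control (64.4 ± 22.8 FPKM, log2 7.24, SE 0.298, adjusted p = 5.19e-06), Mt2, a metallothionein gene (chromosome 8, from 94171970 to 94173568), 93.9-fold (1230 ± 105 FPKM), Cdkn1a 92.9-fold (111 ± 12.8 FPKM) and Fos 73.8-fold (43.9 ± 28.4 FPKM). The largest falls were those of Dbp (0.149 of control), Onecut1 (0.182), Nrep (0.189) and Mid1ip1, a lipogenic cofactor gene (0.23), for which control replicates 1 to 3 were at 4.42, 7.05 and 23.1 FPKM. Nrep lost its call without dmPGE2+APAP replicates 1, 2 or 3 (adjusted p of 0.0963, 0.114 and 0.0818), as did Onecut1 (0.0573, 0.0551 and 0.0542), and Mid1ip1 without dmPGE2+APAP replicate 2 or 3 (0.0602 and 0.0587). Of the panel Hmox1 (22.5-fold), Mt1 (31.8-fold) and Ddit3 (7.84-fold) rose. Without control replicate 3 the log2 fold changes went from 6.55 to 5.04 for Mt2, from 4.99 to 3.96 for Mt1, from 6.54 to 5.72 for Cdkn1a, from −2.46 to −1.69 for Onecut1, from −2.40 to −1.47 for Nrep and from −2.12 to −1.5 for Mid1ip1. Without control replicate 1 they were 7.51 for Mt2, 5.82 for Mt1 and −2.99 for Nrep. Gclc (1.58-fold, adjusted p = 0.0621, and adjusted p = 0.0217 without control replicate 3), Cxcl1 (1.42-fold), Il1b (0.617), Hpgd (0.913), Cyp2e1 (1.01), Alb (1.4), Nqo1 (0.966), Gclm (0.683), Slco2a1 (1.04) and Ptger4 (1.15) did not pass. The log2 fold change of Cxcl1 went from 0.51 to −0.204 without dmPGE2+APAP replicate 1.

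In this comparison 1869 of 11557 genes passed, 1056 higher and 813 lower (56.5% higher), 538 of them at least 2-fold (393 up, 145 down), and 3594 had an unadjusted p under 0.05. With no rescaling 2506 passed and 28.5% were higher. The count fell to 1167 without control replicate 2, 1028 without dmPGE2+APAP replicate 2 and 1134 without dmPGE2+APAP replicate 3.

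Immediate early genes rose in 18 of 19 cases (19 adjusted over the list alone, median log2 fold change 2.98, adjusted p = 3.48e-20, and adjusted p = 0.204 with an estimated correlation), with Jun 22.9-fold and Klf6 6.83-fold above control. In the integrated stress response 13 of 15 genes rose (14 adjusted over the list alone, median 1.93, adjusted p = 3.58e-13, and adjusted p = 0.0122 with an estimated correlation), Gdf15 64.1-fold and Atf4 2.24-fold. Heat shock genes (9 of 14 rose, 11 adjusted over the list alone, median 1.14, adjusted p = 1.96e-07, and adjusted p = 0.35 with an estimated correlation) included Hsph1 (2.89-fold) and Hspb8 (2.86-fold). Of 16 p53 targets 10 rose (adjusted over the list alone, 10 higher and 2 lower, median 0.983, adjusted p = 2.95e-06, and adjusted p = 0.204 with an estimated correlation), Btg2 41.5-fold and Trp53inp1 6.85-fold. Of 16 cAMP and CREB targets 9 rose (10 adjusted over the list alone, median 1.3, adjusted p = 2.95e-06, and adjusted p = 0.204 with an estimated correlation), Nr4a1 61.7-fold (log2 5.95, and 5.27 without dmPGE2+APAP replicate 1). Of 14 NF-kB genes 6 rose (6 adjusted over the list alone, median 0.7, adjusted p = 0.00333, and adjusted p = 0.488 with an estimated correlation), Vcam1 3.26-fold and the NF-kB inhibitor gene Nfkbia 2.42-fold. Of 17 hypoxia genes 5 rose (5 adjusted over the list alone, median 0.279, adjusted p = 0.0113, and adjusted p = 0.204 with an estimated correlation), Ndrg1 3.29-fold.

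Among metabolic lists, gluconeogenesis and fasting genes rose in 6 of 15 cases (8 adjusted over the list alone, median 0.845, adjusted p = 1.83e-05, and adjusted p = 0.488 with an estimated correlation). Igfbp1 rose 25.7-fold, Irs2 2.08-fold and the transcription factor gene Foxo1 1.91-fold. Of 21 fatty acid oxidation genes 3 rose (adjusted over the list alone, 3 higher and 1 lower, median 0.393, adjusted p = 0.0192, and adjusted p = 0.739 with an estimated correlation), Pdk4 11.4-fold. Of 20 cholesterol synthesis genes 0 passed with limma (0 adjusted over the list alone, 8 at an unadjusted p under 0.05) while the list was lower (median −0.495, camera adjusted p = 0.0332, adjusted p = 0.739 with an estimated correlation, fry adjusted p = 0.349). Of 18 pericentral genes 2 fell (2 adjusted over the list alone, median −0.214, adjusted p = 0.0453, and adjusted p = 0.542 with an estimated correlation). The Wnt target gene Tbx3 fell to 0.357 of control, while Glul (259 ± 32.1 against 415 ± 53.5 FPKM) did not pass (adjusted p = 0.107, and adjusted p = 0.027 without rescaling). Of 15 stellate cell markers 3 rose (6 adjusted over the list alone, median 0.403, adjusted p = 0.012, and adjusted p = 0.542 with an estimated correlation), Hgf 1.89-fold and Dcn 1.55-fold. Control replicate 3 again carried part of this: without it the fatty acid oxidation (adjusted p = 0.421) and cholesterol synthesis (0.234) calls were lost. Cholesterol synthesis was also lost without control replicate 2 (0.146) or dmPGE2+APAP replicate 1 (0.0661) or 2 (0.06), and the pericentral call without control replicate 2 (0.0624) or dmPGE2+APAP replicate 1 (0.107) or 2 (0.0671).

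Lists that passed camera in APAP against control and not here were NRF2 and glutathione (3 of 19 rose, 3 adjusted over the list alone, median 0.318, adjusted p = 0.0972, though fry adjusted p = 0.0245), neutrophil markers (2 of 7 rose, 2 adjusted over the list alone, median 1.26, adjusted p = 0.111, fry 0.103) and erythroid and platelet genes (3 of 9 rose, 3 adjusted over the list alone, median 0.209, adjusted p = 0.11, fry 0.103). Itga2b was 2.26-fold and Pf4 2.3-fold above control, and the neutrophil receptor gene Clec4d 3.65-fold. The difference between dmPGE2+APAP and APAP for these lists is the camera test on their direct comparison given above. In total 12 of 35 lists passed (10 higher, 2 lower), and 1 of them with an estimated correlation. In fry 9 of the 12 passed, and fatty acid oxidation (adjusted p = 0.169), cholesterol synthesis (0.349) and pericentral genes (0.0959) did not.

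Of 22984 transcripts 410 passed in dmPGE2+APAP against control (287 higher, 123 lower, 3707 at an unadjusted p under 0.05). With factors from the mRNA table alone 330 were higher and 92 lower, and with factors from the lncRNA table alone 244 and 144. Isoforms of protein-coding genes made up 318 (225 higher, 93 lower), with the parent gene called the same way for 172, transcripts of non-coding genes 45 (28 higher, 17 lower) and assembled transcripts 47 (34 higher, 13 lower). LINC190 was listed at 0 in the controls and at 3.4, 4.39 and 5.53 FPKM here (adjusted p = 0.00113), and isoforms Chka-211, Chka-203 and Chka-205 of the choline kinase gene were 36.1-fold, 31.2-fold and 26.5-fold and Arid5a-206 35.6-fold above control. The largest falls were to 0.0225 of control for Dynlrb1-201, 0.0546 for AC157910.3-201, 0.0752 for Gsta3-204, 0.0819 for Inmt-202 and 0.0967 for Dnase2a-208. Dynlrb1-201 lost its call when any control or dmPGE2+APAP replicate 2 or 3 was left out (adjusted p from 0.0796 to 0.0967) and Dnase2a-208 when any library of the pair was left out (0.067 to 0.115). The log2 fold change of Dynlrb1-201 was −6.38 without dmPGE2+APAP replicate 1 and −4.78 without dmPGE2+APAP replicate 2, that of Chka-211 4.58 without control replicate 3, and that of AC157910.3-201 −4.80 without control replicate 2. Leaving out libraries gave counts of 138, 154 and 179 without control replicates 1 to 3 and 112, 103 and 135 without dmPGE2+APAP replicates 1 to 3. Of the 72 named lncRNA transcripts Snhg3-205 rose (1 adjusted over the list alone, median 0.43, p = 0.0102, and p = 0.0386 with an estimated correlation), a call lost when control replicate 2 or 3 or any dmPGE2+APAP library was left out (adjusted p from 0.078 to 0.13).

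Both treated groups changed many of the same genes against control: 838 were higher in both (119 for independent lists of this size) and 595 lower in both (76.4), and 0 were called in opposite directions. Fold changes correlated across genes with r = 0.879, where unchanged groups against the same controls gave 0.505 in simulation, and genes are not independent replicates. The covariance was 0.322 against a simulated 0.0254, a difference of 0.297. Both comparisons use the same 3 controls. Simulated groups with no change against shared controls gave 0 shared calls in either direction over 50 draws, but a control apart from the others, such as replicate 3, may still add shared calls.

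The question whether dmPGE2 returns APAP-changed genes toward control was asked of the 2393 genes called in APAP against control. With limma 0 of them were called in the opposite direction in dmPGE2+APAP against APAP and 0 in the same direction. The mean of 74.6% of them lay nearer to control with dmPGE2 (Glul, Pf4, Plin2 and Hmox1 are examples), against 60.5% (58.4% to 62.6%) in simulation without a dmPGE2 effect. The simulated spread differs from the real one: the draws called 3520 genes on average (3430 to 3650) where 2393 were observed, and the simulated range treats genes as independent. When the 6 treated libraries were assigned to the groups in other ways the share ran from 49.2% to 78.1%, and 3 of 20 assignments, the real one included, gave 74.6% or more, so an effect of dmPGE2 is not separated from the spread between mice. The median return was 19.1% of the APAP change, against 5.76% in simulation, and 73.7% of the genes had a dmPGE2+APAP mean between the control and APAP means (60.2% in simulation). The covariance of the fold changes was −0.0904 against a simulated −0.0252. Without dmPGE2+APAP replicate 1 the number called in the opposite direction was 35, without APAP replicate 2 it was 2, and without control replicate 2 or APAP replicate 3 it was 1.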

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

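The scores deposited as read counts, pseudocount 0.01, lncRNA scaling from the mRNA table, transcripts of non-coding genes alone, no rescaling for lists and the reversal, and pseudocount 1 for lists, were chosen after seeing the data. Planned fits with edgeR, DESeq2 and limma-voom and filters on counts were not run, because no counts were given. No called list or named gene changed direction under any alternative, while for the other calls only counts were compared. Single named genes were refitted 7518 times in all: 365 fits lost a call, 72 gained a call and 38 changed the sign of an uncalled value. Lists were refitted 444 times, and 80 fits lost a call. Simulated power was lowest for lncRNA: with 200 changed transcripts 1.52% of 4-fold changes were recovered in APAP against control. The real comparison had 824 calls, and more changed transcripts make the adjusted threshold less strict. The 1.52% is therefore not the power of the real comparison.

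For mRNA, requiring a 2-fold change left 688 genes in APAP against control and 538 in dmPGE2+APAP against control. Leaving out libraries gave 1532 to 2296 and 1028 to 1735 genes, with fewer samples, and for dmPGE2+APAP against APAP 0 to 42. Fitting only the 2 groups compared gave 2 genes there, the cause was not tested. On the score tables Gclm (adjusted p = 0.0392) and Il1b (adjusted p = 0.0455) passed in APAP against control.

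For lncRNA in APAP against control, no filter gave 527 calls, non-coding genes alone 113 of fewer transcripts tested, and left-out libraries 181 to 454. In dmPGE2+APAP against control, only the 2 groups gave 225, pseudocount 1 268, non-coding genes alone 55 and left-out libraries 103 to 179. In dmPGE2+APAP against APAP, pseudocount 1 gave 2 calls (Thoc7-203, Hdac1-203), pseudocount 0.01 gave 3 (Med1-207, Banf1-204, Fhad1-208), the deposited scores 8, non-coding genes alone 1 (Gm11827-201) and left-out libraries 1 to 8. The cause was not tested.

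With an estimated correlation 1, 0 and 1 lists passed in APAP against control, dmPGE2+APAP against APAP and dmPGE2+APAP against control. Part of this comes from the 6 residual degrees of freedom that camera uses with an estimate. The estimates had a median of 0.213 over the 35 lists, above the preset 0.01, and ran from −0.0238 (circadian clock) to 0.627 (cholesterol synthesis). For lists with larger estimates the p values at the preset correlation may be too small. How much of the loss comes from correlation was not tested. Hypoxia genes lost their call in APAP against control with an estimate (0.00998) no larger than the preset value. In APAP against control fry lost cholesterol synthesis (adjusted p = 0.24) and fatty acid oxidation (0.0734) and gained cell death (0.0012) and ferroptosis (0.00224). In dmPGE2+APAP against APAP fry gave 0 and pseudocount 1 gave 16, and left-out libraries gave 3 to 14. In the other comparisons left-out libraries gave 12 to 18 and 10 to 15. For dmPGE2+APAP against control, the pericentral call was also lost with median-of-ratios scaling (adjusted p = 0.0553) and without rescaling (0.126), as was cholesterol synthesis without rescaling (0.126).

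The share of APAP-changed genes nearer to control was 77.5% for 2-fold changes, 71.9% without rescaling and 72.5% to 81.3% without a library, and 0 to 35 genes were called in the opposite direction.

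Replicate numbers are shared by the groups. Each library's deviations from its group mean were correlated across genes with those of the same-numbered libraries of other groups. These correlations were −0.117 to 0.0716, so the libraries are not read as pairs. The deviations of a control and an APAP library of the same number correlated best in 3 of 3 cases, those of control and dmPGE2+APAP in 0 of 3, and those of APAP and dmPGE2+APAP in 1 of 3. With the replicate number as a block, mRNA calls were 2025, 0 and 1490, lncRNA calls 435, 0 and 108, lists 15, 15 and 12, and the reversal 0 genes and 75%.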

Other observations

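All tests of explanations below were chosen after the results were seen. The circadian clock list moved in both directions. In APAP livers 5 of 17 clock genes rose and 4 fell (adjusted over the list alone, 7 and 7), so the median (−0.309), the mean (0.0105) and the test (lower, adjusted p = 0.892) differ in sign. The repressor gene Nfil3 rose 4.84-fold to 36 ± 1.47 FPKM, and the output genes Per3, Tef and Dbp fell to 0.188, 0.473 and 0.0985 of control. With dmPGE2, 7 rose and 4 fell against control (adjusted over the list alone, 8 higher and 6 lower, median 0.381, adjusted p = 0.701), with the core clock gene Arntl at 8.88 ± 0.75 FPKM against 1.37 ± 0.878 (7.9-fold, log2 2.98, and 2.33 without control replicate 3). Arntl was also high with APAP alone, at 5.90, 8.38 and 7.56 FPKM in replicates 1 to 3. Between dmPGE2+APAP and APAP 0 of 17 clock genes passed (1 adjusted over the list alone, median 0.0944, camera adjusted p = 0.405). Of 18 cell death genes 7 rose and 1 fell in APAP livers (adjusted over the list alone, 7 higher and 2 lower, median 0.344, adjusted p = 0.173). The TWEAK receptor gene Tnfrsf12a rose 8.98-fold to 31.6 ± 8.27 FPKM and the survival genes Mcl1 and Bcl2l1 rose 1.71-fold and 2.22-fold, while the death gene Bmf fell to 0.486 of control. With dmPGE2 Tnfrsf12a was at 17 ± 3.88 FPKM, 4.98-fold above control.

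Cebpa and Foxa2, which encode transcription factors of hepatocytes, fell to 0.667 and 0.626 of control with APAP and to 0.676 and 0.463 with dmPGE2 and APAP. They are part of the 5 of 17 hepatocyte secreted and identity genes that fell in each comparison (adjusted over the list alone, 1 higher and 5 lower in each). The list's medians (0.019 and 0.137) lie above 0 and its means (−0.198 and −0.19) and tests below it (adjusted p of 0.659 and 0.687). In sinusoidal endothelium 2 of 16 genes rose and 2 fell with APAP (4 adjusted over the list alone, median 0.0198, adjusted p = 0.723): Lyve1, a hyaluronan receptor gene, rose 3.53-fold to 13.6 ± 2.16 FPKM, and Gpr182 and the VEGF receptor gene Kdr fell to 0.535 and 0.652 of control. With dmPGE2 Lyve1 was at 22.8 ± 5.4 FPKM, 5.96-fold above control. Of 18 periportal genes 2 rose and 2 fell with APAP (adjusted over the list alone, 3 higher and 2 lower, median 0.0748, adjusted p = 0.775), with Igf1 at 0.533 of control and Hsd17b13 1.59-fold higher. Of 12 cell cycle genes 2 rose and 1 fell (3 adjusted over the list alone, median 0.0863, adjusted p = 0.314): Pcna rose 1.42-fold and Mcm5 3.79-fold, and the cyclin gene Ccnd1 fell to 0.443 of control.

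Platelet genes were higher in APAP livers (median log2 fold change 2.64, range 1.99 to 4.11) and lower again with dmPGE2 (−1.56, range −2.49 to −0.816). More blood left in the APAP livers would raise globin genes alike, and their median of 0.952 (range 0.752 to 1.08, SE up to 0.349) argues against it as the whole cause of the rise. A smaller share of hepatocyte RNA would raise all other cell types alike, and among stellate, Kupffer, endothelial, monocyte and cholangiocyte lists the largest median, 0.527 for stellate cells, argues against it as the whole cause (neutrophil markers, at 2.14, were not part of that test). For the fall with dmPGE2, the globin median of −1.01 is consistent with less blood in those livers. Whether the platelet RNA came from tissue or from blood stays open, and platelet counts in sections of perfused livers would decide it.

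Control replicate 3 differed from the other controls: Cyp4a14 was at 10.4 FPKM against 2250 and 2500, Thrsp at 164 against 6.81 and 10.5, and Scd1 at 1320 against 239 and 202. A GC or length bias of the library is not supported, since its deviations correlated across genes with GC content or length by at most 0.0284 in size (rho, 0.298 with length in APAP replicate 3, the largest of the other libraries). The lipogenesis median minus the fatty acid oxidation median was 1.82 (log2), which is consistent with a fed rather than fasted animal. The largest size in another library was 1.02, in control replicate 1 and in the opposite direction (−1.02, taken partly against control replicate 3), and the highest signed value was 0.117 in APAP replicate 3. The labels give no feeding state, so this may or may not be the cause.

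Replicate 1 of dmPGE2+APAP lay midway between the treated groups, at 0.495 on the axis from the other APAP libraries (0) to the other dmPGE2+APAP libraries (1). APAP replicate 2 lay at 0.498, so their difference of −0.003 leaves open an exchange of these labels, and the 2 cannot be told apart by position. With the labels exchanged 1120 genes instead of 1082 had an unadjusted p under 0.05, and 0 passed adjusted in limma either way. The exchange also gave more calls against control (2491 against 2393) and a larger share of genes nearer to control (78.1% against 74.6%), the highest of all 20 assignments. A weaker effect of dmPGE2 in that mouse was not tested and may account for it as well.

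With 3 against 3 libraries there are 10 splits of the samples, too few for a share under 0.05, so only values are given. The real split gave 2393 mRNA calls in APAP against control (highest other split 1, 1 of 10 as large), 0 in dmPGE2+APAP against APAP (highest other 1, 10 of 10 as large) and 1869 in dmPGE2+APAP against control (highest other 1, 1 of 10). For lncRNA the values were 824 (highest other 5, 1 of 10), 0 (highest other 8, 10 of 10) and 410 (highest other 7, 1 of 10). For lists they were 15 (highest other 17, 4 of 10), 10 (highest other 14, 4 of 10) and 12 (highest other 14, 3 of 10). For the share of genes nearer to control, 3 of 20 assignments of the treated libraries gave 74.6% or more (highest other 78.1%, the exchange above).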
